A study of Homo sapiens with 6 samples.

How the data were processed

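The series holds 6 one-colour microarrays of A549, a human lung adenocarcinoma cell line, treated for 6 h with pirfenidone, an oral antifibrotic drug, at 1.5 mg/ml, or with an equal volume of phosphate-buffered saline (PBS). Each treatment has 3 replicates, numbered 1 to 3 in the labels. Total RNA was labelled with Cy3, per the labels' protocols. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

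Per the file headers, each array was scanned in 1 channel and quantified with Agilent Feature Extraction 11.5.1.1 on array design 026652, annotated on genome build hg19. The deposited scanner files give spot intensity on a linear scale, and the processed intensity is the background-subtracted and detrended signal of each spot. A deposited table of the whole series gives log2 values. Its differences between arrays matched those of the scaled scanner values with a slope of 1 on every array, so its scale is log2 with each array set to its 75th percentile and each probe centred over the arrays. Its column medians were -0.06, 0.03 and -0.02 for PBS replicates 1 to 3 and -0.13, 0.09 and 0.04 for pirfenidone replicates 1 to 3. What it was made with is not given in the sources used here, and it served only as an alternative.

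Each array holds 44495 spots, of which 43118 are not controls and belong to 34127 probes. The log2 processed intensity of every spot was reduced by that array's 75th percentile, spots flagged as outliers by the scanner software were left out, and the spots of a probe were averaged. Probes were named through their transcript accession in a RefSeq table of another genome assembly than the array's, so no coordinates are given. In all, 26377 probes matched a gene and 7750 kept the name in the files. Of 27527 genes or unnamed transcripts, each represented by its probe with the highest mean over all 6 arrays, 9724 were not well above background on at least 3 of the 6 arrays and 16 lacked a value on an array. The remaining 17787 were tested, 14564 of them with a symbol. Of the genes called, CHAC1, ULBP1 and PCK2 each had 2 probes above background, which moved the same way, with log2 changes of 2.95 and 3.12, 1.98 and 2.30, and 1.27 and 1.53.

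The comparison was pirfenidone against PBS, with no other term in the model. It was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A standard error (SE) is that of the moderated fit. Gene lists were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 30 lists. The same test with a correlation estimated from the data and fry, which asks whether a list's genes move on balance in one direction, were run beside it. The lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per direction, up to 8 genes past the threshold with the largest change, filled up to 8 by the lowest p among genes that did not pass. These had to have groups that did not overlap and a probe well above background on all 3 arrays of the higher group. It also takes the leading called members of each list and 10 genes given in advance, of which 1 is not reported here. Other list members named here were chosen after their values were seen, as examples. The tests were tried on simulated data with the real means and moderated spreads of the 17787 genes, drawn independently for each gene and array. The simulation held no correlation between genes and no replicate pairs, so its false calls cannot stand for those in the real data. The limma fit called 22 of 67 genes changed by a log2 of 1, 53 of 67 changed by 2 and 62 of 66 changed by 3, with 4 false calls, and camera called a list shifted by 0.5 and 1 of 29 unshifted lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The median of a list was also placed among those of 10000 random lists of the same size matched on mean signal, without the list's own members where this was done within replicate pairs.

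The replicate numbers pair the samples. Deviations from the group means correlated across genes at 0.63, 0.61 and 0.72 between arrays of the same number, and below 0 between arrays of different numbers. Centring on the group means forces the latter below 0 on average once the former are positive, so only the former bear on the pairing. The names of the deposited files give both arrays of a number the same day and differ between numbers, without saying what was done on that day. The fit without the number as a term stayed the main one, as fixed, and the fit with it is given where it changes a call. Replicate 1 of both groups lay on slide 1 and replicates 2 and 3 of both groups on slide 2.

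The 75th percentile of the processed intensity was 3160, 1981 and 1497 on PBS replicates 1 to 3 and 3164, 2490 and 2547 on pirfenidone replicates 1 to 3. Between 65.1% and 69.4% of spots were well above background, and none was saturated. PBS replicate 3 was the weakest array. Its median spot variation before detrending was 18.5%, against 8.23% to 13.2% on the others, and 35429 of its spots were found where the grid placed them, against at least 41261 on the others. The number of arrays limits the precision.

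Alternatives were normexp background correction with quantile normalization, quantile normalization alone, median scaling, the series table, no filter on dim probes or a filter on all 6 arrays, and flagged spots kept. The mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, the replicate number or the slide as a block, the slide of replicates 2 and 3 alone, and each array or pair left out in turn were also run. The mean pixel signal is not used here, so normexp worked on the median spot and background signals. It added an offset of 50, which shrinks the log2 changes of dim probes.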

Results

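The expression of 17787 genes and unnamed transcripts was measured in A549 lung adenocarcinoma cells after 6 h with 1.5 mg/ml pirfenidone or with PBS, on 3 arrays per group. Between 62.3% and 67% of probes were well above background on an array. The comparison asks which transcripts the drug changed at this dose and time.

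With pirfenidone, camera at the preset correlation called genes of the integrated stress response and of the unfolded protein response higher as groups. It called heat shock and cell cycle genes lower as groups. Camera called 13 of 30 lists, 6 higher and 7 lower, but 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 3, the ATF4, heat shock and MYC lists. Other splits of the 6 arrays into 3 and 3 gave 6 to 13 lists in camera. Of single genes, 6 rose and 3 fell (limma, adjusted p under 0.05), all but ABHD13, for which there is only a lower bound, by at least 2-fold. Of these, CHAC1, which encodes a glutathione-degrading enzyme, rose most, by a log2 of 2.95 ± 0.27 (SE, n = 3 per group) or 7.73-fold. DNAJB9, a co-chaperone of the endoplasmic reticulum, rose by 2.53 ± 0.18, FUT1, a fucosyltransferase, by 2.51 ± 0.18, and ULBP1, a ligand of the natural killer cell receptor NKG2D, by 2.30 ± 0.14. TRIB3, a pseudokinase, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 1.66 ± 0.13 and 1.53 ± 0.14. HPDL, a mitochondrial dioxygenase-like protein, fell by 1.54 ± 0.14, and CYP26A1, which breaks down retinoic acid, fell by 1.51 ± 0.12. ABHD13, a member of the hydrolase family, was not well above background on any pirfenidone array and was at least 1.34-fold lower there, taking for each dim array the higher of its own value and the lowest signal of a probe well above background. Under normexp, here background correction followed by quantile normalization, FUT1 changed by 1.17 and still passed, while ABHD13 changed by -0.17, which is less than that bound, and did not pass. The adjusted p of these 9 genes lay between 0.0358 and 0.0493 in limma. Each moved the same way in 3 of 3 replicate pairs, which follows from their groups not overlapping.

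**Figure D1:**
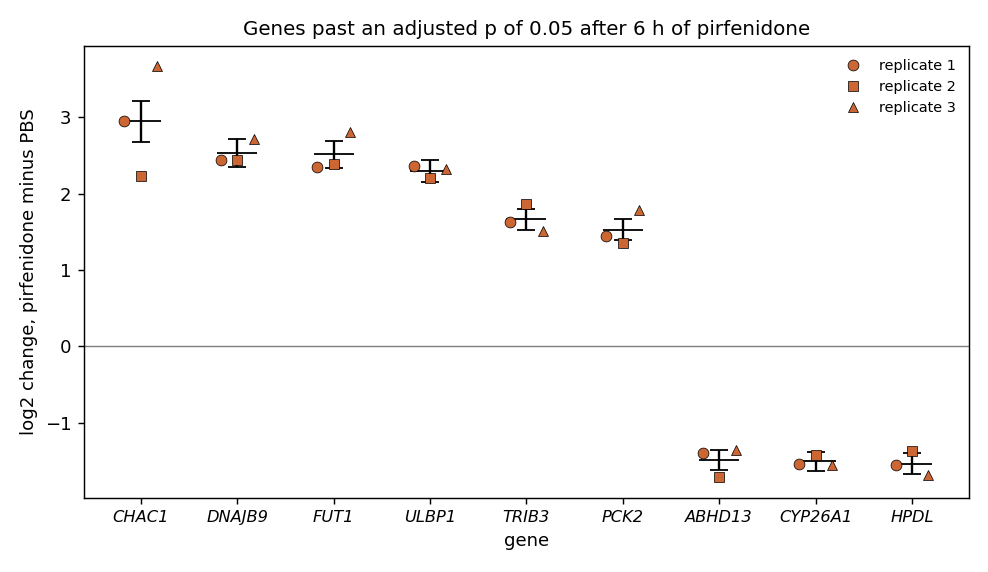
The y axis gives the log2 change, pirfenidone minus PBS, of the 9 genes past the threshold on the x axis. Symbols are the 3 replicate pairs, and the bar and whiskers are the mean and its SE from limma. All 3 pairs of each gene lie on one side of 0, as they must where the groups do not overlap, with CHAC1 ranging most, from 2.24 to 3.67.

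At an adjusted p under 0.1, 36 genes passed in limma, 20 higher and 16 lower, and 2682 had an unadjusted p under 0.05. Groups did not overlap for 4027 genes, or 22.6%, where chance gives 10% for 3 unpaired arrays against 3. The other splits of the arrays that part all 3 replicate pairs gave 1.09% to 3.13%, and the splits that part 1 pair up to 20.5%. Among the genes next in line, none of which passed, FICD, which modifies the chaperone BiP, gave 1.81 ± 0.18, and HERPUD1, of endoplasmic reticulum-associated degradation, gave 1.74 ± 0.18. On the lower side, DGAT2, which makes triglycerides and was well above background on 2 of 3 pirfenidone arrays, gave -2.78 ± 0.32 (-0.97 under normexp, where it passed), FAM111B, a protease, -1.87 ± 0.22, E2F8, a cell cycle repressor, -1.20 ± 0.14, HSPA8, the constitutive HSP70, -1.1 ± 0.13, and CXCL1, a neutrophil chemokine, -1.03 ± 0.13. The number of calls moved with the settings. With the replicate number as a block 2 genes passed, ULBP1 and DNAJB9, with the slide as a block or within slide 2 none did (3076 and 862 at an unadjusted p under 0.05 in limma), and with any 1 array or pair left out none did (862 to 3066 at an unadjusted p under 0.05), except that 766 passed without pirfenidone replicate 2, among them all 9. Median scaling and the series table each gave 6 higher and 1 lower.

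The list of ATF4 targets and the integrated stress response, the programme that cells switch on when amino acids run short or proteins misfold, rose with the lowest p of all lists. Camera gave it an adjusted p of 2.21e-17, against an adjusted p = 0.225 with an estimated correlation. Of 30 members, 29 had a change above 0 and the median was 0.54. Over all genes CHAC1 and TRIB3 passed, and adjusted over the list alone 19 members rose and none fell (limma). Among these were the transcription factors DDIT3 (CHOP), at 3.39 ± 0.54, and ATF3, at 1.96 ± 0.53, the mTOR inhibitors SESN2 and DDIT4, at 2.34 ± 0.30 and 1.88 ± 0.25, and enzymes of asparagine, serine and folate metabolism, with ASNS at 0.82 ± 0.12, PHGDH at 0.86 ± 0.19 and MTHFD2 at 0.80 ± 0.15. The transcript of ATF4 itself stood at 0.14 ± 0.13, and the amino acid transporter SLC7A5 was the 1 member below 0. The list's median was 0.60, 0.69 and 0.56 in replicate pairs 1 to 3, and so 0.60 on slide 1. On slide 2 the median of the members' mean changes over both pairs was 0.52.

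Genes for endoplasmic reticulum chaperones and the unfolded protein response also rose as a list, with a median of 0.38 and 21 of 24 members above 0. Camera gave an adjusted p of 6.55e-08, and an adjusted p = 0.527 with an estimated correlation. DNAJB9 passed over all genes, and adjusted over the list alone 6 members rose and none fell (limma). These were DNAJB9, HERPUD1, the stress sensor ERN1 (IRE1) at 1.46 ± 0.37, its target XBP1 at 0.97 ± 0.20, the transport protein SEC24D at 1.43 ± 0.33 and the transcription factor CREB3L2 at 0.86 ± 0.21. The classical chaperones HSPA5 (BiP), HSP90B1 and CALR stood at 0.62 ± 0.26, -0.00096 ± 0.14 and -0.08 ± 0.15 and did not pass. The list's median was 0.20, 0.73 and 0.28 in pairs 1 to 3.

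Heat shock proteins fell as a list, with 18 of 20 members below 0 and a median of -0.38. Camera gave the list an adjusted p of 1.92e-06, and an adjusted p = 0.315 with an estimated correlation. Adjusted over the list alone 7 members fell and none rose, while none passed over all genes (limma). HSPA1A, the inducible HSP70, fell by 2.96 ± 0.89, HSPA6 by 1.96 ± 0.53, the co-chaperone DNAJB1 by 1.18 ± 0.25 and HSPA8 by 1.1 ± 0.13. HSPA1A gave -1.21 in pair 2, against -3.81 and -3.87 in pairs 1 and 3. The list's median was -0.26 after quantile normalization alone and -0.25 under normexp, which includes it.

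**Figure D2:**
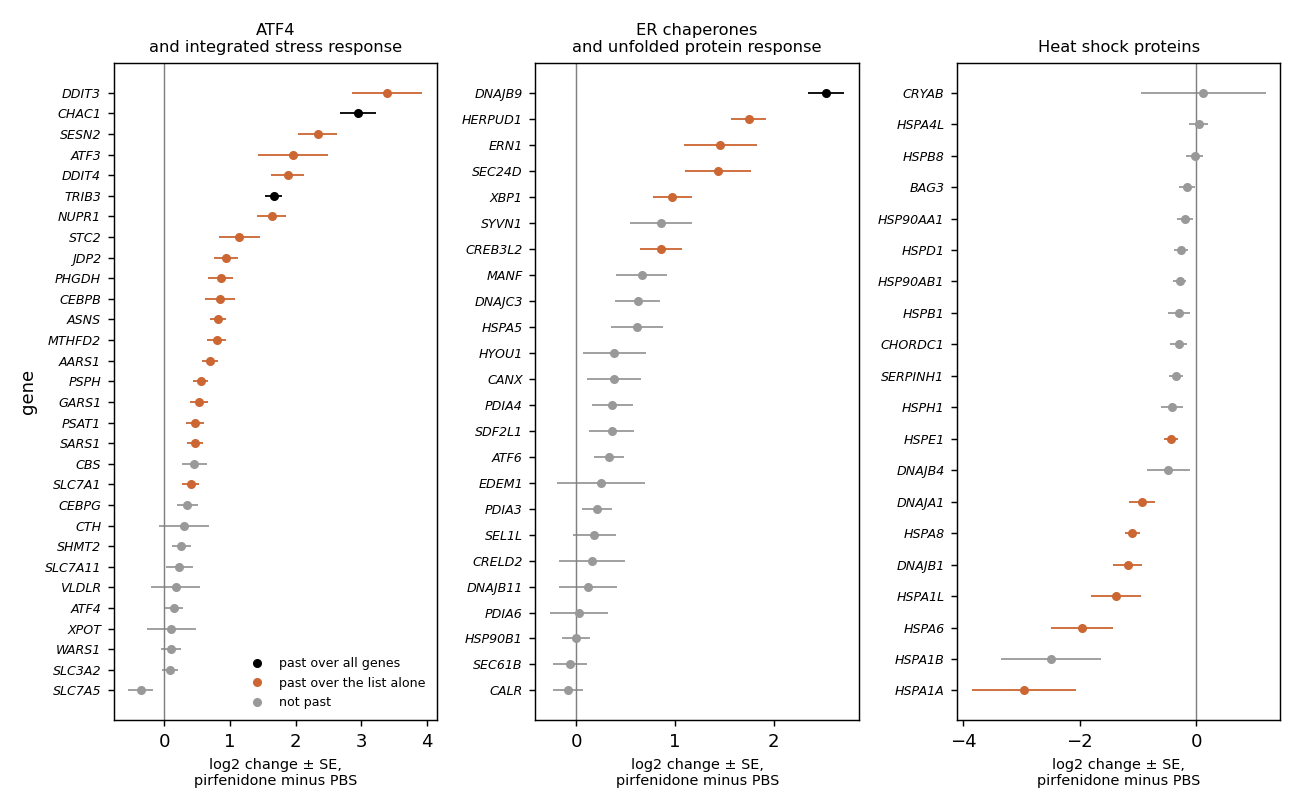
Each panel shows the measured members of a gene list on the y axis against their log2 change, pirfenidone minus PBS, with the SE from limma, n = 3 per group. Colours mark members past the threshold over all genes, over the list alone or not at all. Of the ATF4 list 29 of 30 members lie above 0, of the endoplasmic reticulum list 21 of 24, and of the heat shock list 2 of 20.

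Genes of the G1 to S transition and DNA replication fell as a list, with 33 of 35 below 0 and a median of -0.33. Camera gave an adjusted p of 6.34e-08, and an adjusted p = 0.527 with an estimated correlation. None passed over all genes, and adjusted over the list alone 7 fell and none rose (limma), among them E2F8, the phosphatase CDC25A at -1.04 ± 0.18, cyclin CCNE2 at -0.86 ± 0.22 and the flap endonuclease FEN1 at -0.75 ± 0.16. Of 35 genes of G2 and mitosis 32 were below 0, with a median of -0.32, and none passed over all genes or adjusted over the list alone. Camera called this list at an adjusted p of 4.39e-05, with an adjusted p = 0.578 with an estimated correlation, and its median was -0.17 without pirfenidone replicate 1 and -0.20 after quantile normalization. MYC targets and ribosome biogenesis genes fell by a median of 0.22, with 30 of 33 below 0 and, adjusted over the list alone, 3 lower, RRS1, ODC1 and NOP56. Camera gave an adjusted p of 4.79e-05, and an adjusted p = 0.259 with an estimated correlation, and the median was -0.12 after quantile normalization.

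Immediate early and MAPK feedback genes, circadian and glucocorticoid response genes and targets of SREBP2, the regulator of cholesterol synthesis, rose as lists, with medians of 0.36, 0.34 and 0.26 and camera adjusted p of 6.79e-06, 0.000464 and 4.83e-05. With an estimated correlation their adjusted p was 0.527, 0.527 and 0.578. None of their members passed over all genes, and adjusted over the list alone 0 of 38, 6 of 23 and 1 of 25 rose and none fell (limma). The circadian and glucocorticoid genes that rose included TSC22D3 (GILZ), at 1.86 ± 0.31, and the clock genes PER1, at 1.36 ± 0.32, and NR1D2, at 1.08 ± 0.31, and the SREBP2 target was STARD4, a cholesterol carrier, at 0.76 ± 0.14. The immediate early list had a median of 0.61 and 0.38 in pairs 1 and 3 but -0.02 in pair 2, and the circadian list 0.48 and 0.61 but 0.05. The growth factor gene HBEGF and the transcription factor gene EGR1 gave 0.07 and -0.34 in pair 2, against at least 1.55 and 2.26 in pairs 1 and 3. Differences between pairs were not tested. Single arrays moved the medians, which were 0.18 for the immediate early list without pirfenidone replicate 1 (0.20 without both arrays of replicate 1), 0.40 and 0.17 for SREBP2 targets without PBS replicate 3 and without pirfenidone replicate 3, and 0.57 and 0.17 for the circadian list without PBS replicates 2 and 3 in turn. The circadian list's median was 0.55 without both arrays of replicate 2 and 0.19 under normexp.

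The list of p53 targets was called as higher by camera (adjusted p 0.0162, median 0.10), with an adjusted p = 0.552 with an estimated correlation. Its members went both ways, with 8 higher and 3 lower adjusted over the list alone and none past the threshold over all genes (limma). The higher ones included SESN2, which is also on the ATF4 list, the cell death genes BBC3 (PUMA) at 1.56 ± 0.34 and PMAIP1 (NOXA) at 1.02 ± 0.24, and CDKN1A (p21) at 1.01 ± 0.28. The lower ones were ZMAT3 at -1.47 ± 0.26, PLK2 at -0.73 ± 0.16 and TRIAP1 at -0.67 ± 0.19. YAP and TEAD targets were called as lower by camera (adjusted p 0.0162, median -0.17), with an adjusted p = 0.556 with an estimated correlation. They had none past the threshold over all genes and 4 of 24 lower adjusted over the list alone, ANKRD1, FJX1, TGFB2 and NUAK2. The p53 median was 0.17 without PBS replicate 2, 0.055 without pirfenidone replicate 1, 0.21 and 0.062 without both arrays of replicate 2 or 3, and 0.21 with the mean of a gene's probes. It was no longer called without PBS replicate 3 or without both arrays of replicate 1. The YAP median was -0.095, -0.11 and -0.11 without PBS replicate 1, PBS replicate 3 and pirfenidone replicate 3, and -0.10 without both arrays of replicate 3, after quantile normalization and under normexp. Its call was lost without PBS replicate 3, without pirfenidone replicate 2, without both arrays of replicate 3 and with every probe on its own. With the replicate number as a block camera called 11 lists rather than 13, and the p53 and YAP lists were those lost, at an adjusted p of 0.0921 and 0.121.

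Ribosomal protein genes and nuclear genes of oxidative phosphorylation were called as lower by camera, with medians of -0.21 and -0.16 and adjusted p of 5.26e-06 and 0.00112, or an adjusted p = 0.578 with an estimated correlation for both. All 56 ribosomal protein genes and 35 of 37 oxidative phosphorylation genes lay below 0, and none passed over all genes or adjusted over the list alone (limma). Over all arrays these shifts did not stand apart from those of equally bright genes, since the medians lay at percentiles 35.6 and 41.3 of random lists matched on mean signal. Within replicate pairs 1 to 3 the ribosomal median lay at percentiles 100, 1.9 and 0.26. The ribosomal median was -0.31 without both arrays of replicate 1 and -0.13 without those of replicate 3, and the oxidative phosphorylation list was not called without PBS replicate 3 or without pirfenidone replicate 2. After quantile normalization the medians were -0.01 and -0.03, under normexp -0.010 and -0.018, neither list was called in either, and camera's direction for the ribosomal proteins turned under normexp.

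**Figure D3:**
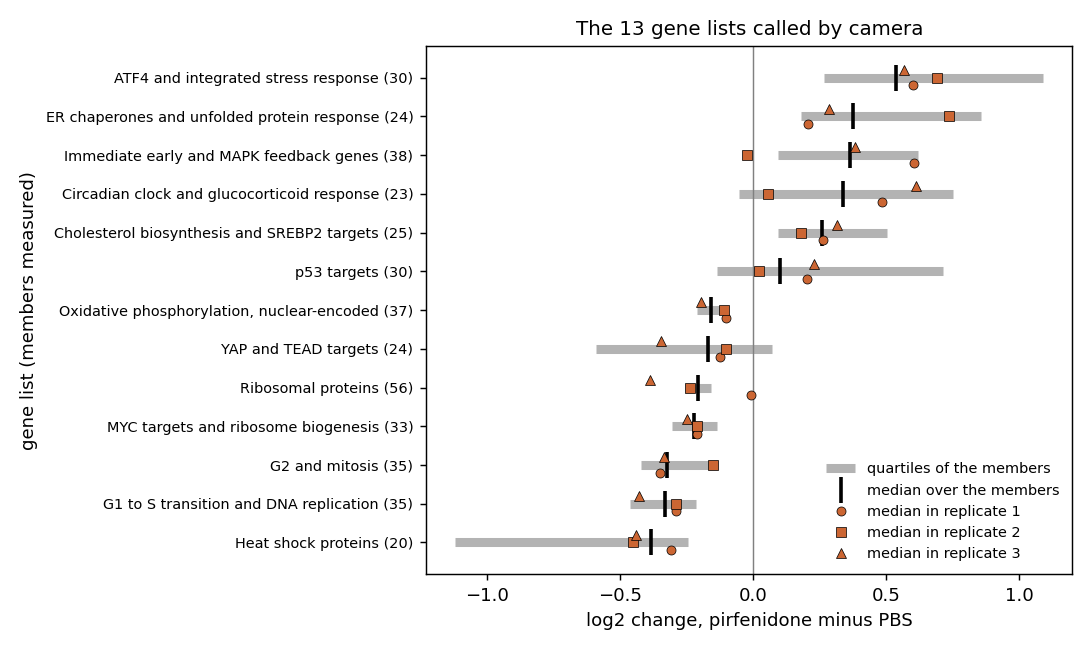
The x axis gives the log2 change, pirfenidone minus PBS, of the 13 gene lists called by camera on the y axis. Black ticks are medians over the members, grey bars their quartiles and symbols the medians in the 3 replicate pairs. The ATF4 list lies between 0.56 and 0.69 in all pairs, while the immediate early list is at -0.02 in pair 2 and the ribosomal proteins are at -0.01 in pair 1.

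The genes given in advance for fibrosis, drug metabolism and immune control that are reported here did not pass. TGFB1 gave 0.20 ± 0.22, TGFB2 -0.74 ± 0.15, SMAD7 0.23 ± 0.15 and COL1A1 0.21 ± 0.61. CYP1A1, a target of the aryl hydrocarbon receptor, gave -0.58 ± 0.26 and CD274 (PD-L1) -0.20 ± 0.53. The reference genes GAPDH and ACTB gave -0.16 ± 0.15 and -0.03 ± 0.13, and both turned above 0 after quantile normalization, ACTB also under normexp. Of the 17 lists not called, TGF-beta and SMAD response genes came nearest, at an adjusted p of 0.0963 in camera and a median of 0.17, followed by replication-dependent histones at 0.11 and 0.17, NRF2 targets at 0.142 and -0.15 and WNT targets at 0.155 and -0.24. Collagen and matrix genes (median -0.12), mesenchymal transition genes (-0.09), epithelial junctions and keratins (-0.07) and the alveolar lineage (-0.10) had adjusted p from 0.406 to 0.916. Aryl hydrocarbon receptor targets (-0.20), antigen presentation (-0.11), hypoxia and glycolysis (-0.13), interferon-stimulated genes (0.02), fatty acid synthesis and lipid storage (0.04), cytokines and NF-kB targets (0.05) and metallothioneins (-0.03) were not called, with adjusted p from 0.255 to 0.916. Test, mean and median differed in sign for the mesenchymal, fatty acid and cytokine lists. Markers of other cell types were not called either, with medians of -0.09 for 5 genes of fibroblasts and endothelium and -0.20 for 12 genes of leukocytes and erythroid cells.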

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

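The called genes kept their direction in every setting that tested them (ABHD13 was not tested with the filter on all 6 arrays), while their number varied. Their groups did not overlap, so leaving out arrays or pairs could not turn a sign. The blocks and the eBayes settings leave the fitted change as it is. Beside 9 genes (6 higher, 3 lower, 9 at least 2-fold by fitted values, as in all such counts here, although ABHD13 has only a bound of 1.34-fold) and 13 lists, normexp with quantile normalization called 21 (13 higher, 8 lower, 16 at least 2-fold), 7 of them shared, and eBayes with trend and robust settings 22 (15, 7 and 21), 8 of them shared. The mean of a gene's probes gave 5 (1 lower, 5 at least 2-fold), every probe on its own 3 (3 higher, 0 lower, 3 at least 2-fold), and median scaling and the series' own values gave 1 lower gene each. With no filter on dim probes limma called 0 genes in either direction or at least 2-fold (2345 at an unadjusted p under 0.05) among 27493 tested. With the replicate number as a block, which spends degrees of freedom on the pairs, 2 genes passed (2 higher, 0 lower, 2 at least 2-fold), with 5109 at an unadjusted p under 0.05. It ended no list call but those of the p53 and YAP lists, whose adjusted p ranged from 0.00767 to 0.0921 and from 0.00106 to 0.125 over the alternatives. The slide as a block and slide 2 alone gave 0 genes higher, lower or at least 2-fold in limma (3076 and 862 at an unadjusted p under 0.05). In limma, an adjusted p under 0.01 gave 0 and under 0.1 gave 36. Of the lists, 0 passed with an estimated correlation, 3 of them at an unadjusted p under 0.05, and fry called 3. Leaving out 1 array or pair gave 0 to 766 genes, 0 to 333 higher, 0 to 433 lower and 0 to 485 at least 2-fold. The cause was not tested, beyond the smaller number of samples. Of the 13 lists, 9 were called in all 22 alternatives that kept the preset correlation, the ATF4 list with medians from 0.52 to 0.65. These are not 22 separate checks. The eBayes settings do not enter camera, and slide 2 alone is the same fit as that without replicate 1. The ribosomal protein list had a median of -0.010 and the opposite camera direction under normexp, and its adjusted p ranged from 9.52e-13 to 0.996. Signs also turned for genes that never passed. GAPDH was at 0.041 after quantile normalization, and ACTB at 0.16 after quantile normalization and 0.18 under normexp. Leaving out arrays or pairs moved TGFB1 from -0.022 to 0.328, COL1A1 from -0.39 to 0.70, CD274 from -0.71 to 0.34 and ACTB from -0.118 to 0.092. The cause was not tested. Among the single genes named by the rule fixed in advance, a setting brought a value past the threshold in 19 cases and ended a call in 124, and it ended a list call in 14 with the direction kept and in 1, the ribosomal list under normexp, with it turned.

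With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 9 genes against at most 3 in another, and 1 of the 10 splits gave as many. For genes higher this was 6 against 3 and 1 split, for genes lower 3 against 3 and 2 splits, for genes at least 2-fold 9 against 3 and 1 split, and for lists 13 against 13 and 2 splits. The other split with 13 lists set PBS replicates 1 and 3 with pirfenidone replicate 1 against the rest. Of the 4 splits that part all 3 pairs, those other than the real one gave 0 genes in limma and at most 11 lists, while the remaining 6 splits part 1 pair.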

Other observations

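Tests of the slide, of a ribosomal response shared by all pairs, of brightness within pairs, of signal scale and mixing in replicate 2 and of the zinc finger genes were chosen after the result was seen, and the others before.

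Aminoacyl-tRNA synthetase genes split. The 12 synthetases known as ATF4 targets had a mean change of 0.21, with 10 above 0, and the 24 others, most of them mitochondrial, a mean of -0.22, with 5 above 0. The difference of 0.43 had a two-sided permutation p of 0.00015 across genes, which are not independent replicates (adjusted p 0.0003 over 2 tests). Without the 4 members already on the ATF4 list it was 0.31, at a permutation p of 0.00913. Over the scalings run, the difference lay between 0.37 and 0.45. AARS1 gave 0.70 ± 0.12, CARS1 0.63 ± 0.12 and YARS1 0.38 ± 0.13, while mitochondrial RARS2 and CARS2 gave -0.60 ± 0.15 and -0.58 ± 0.14. No synthetase passed over all genes in limma, and MARS1, of the ATF4 group, went the other way at -0.60 ± 0.16. ATF4-linked selectivity is a candidate explanation, found among genes whose wider list had already been seen to rise. The 12 targets are cytosolic and most of the others mitochondrial, so a difference by compartment was not separated from it.

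Some members of 3 lists that were not called are given as values, since the lists went both ways and none of these genes passed over all genes. In the fatty acid list, with 13 of 23 members above 0, limma adjusted over the list alone called DGAT2, at -2.78 ± 0.32, and the fatty acid elongase ELOVL6, at -0.54 ± 0.12, lower and the phosphatidate phosphatase LPIN1, at 1.07 ± 0.22, higher. DGAT2 was well above background on 2 of 3 pirfenidone arrays and gave -0.97 under normexp. In the WNT list, with 5 of 14 above 0, the feedback genes AXIN2 and RNF43 gave -1.53 ± 0.42 and -1.21 ± 0.36, and in the cytokine list, with 14 of 26 above 0, the chemokines CCL2 and CXCL5 gave -1.41 ± 0.36 and -1.11 ± 0.27. Adjusted over the list alone, no member of the WNT list passed and only CXCL1 of the cytokine list did (limma), so the WNT and chemokine genes given here did not. The genes given from all 3 lists were chosen after their values were seen. By the cut of 0.5 set in advance, no rise of the family was seen beside that of ULBP1. Of 5 other NKG2D ligands measured, 1 had a change above 0.5, ULBP3 at 0.50 ± 0.53. Of the 5, 3 were above 0, with ULBP2 at 0.401 ± 0.395, and SEs of this size do not exclude a smaller rise. For CYP26A1, a general loss of retinoic acid signalling was not settled. The 14 other retinoic acid targets had a median of -0.12, with 4 above 0, and RARA, one of these, stood at 1.04 ± 0.30.

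Replicate pair 2 held 376 genes changed at least 2-fold against 1149 and 1271 in pairs 1 and 3, and over the 963 genes that those pairs moved the same way and by at least 2-fold on average, the slope of pair 2 on their mean was 0.34. A compressed signal scale or RNA mixed from the PBS sample would shrink every list. As the only cause, the first is argued against by the ATF4 list, whose median in pair 2 was 1.18 times the mean of the other pairs. The second is argued against in the same way by the endoplasmic reticulum list, at 3.0 times. Both lists were picked after their pair medians were seen. Some other lists shrank in pair 2, such as the immediate early list, at -0.02 against 0.61 and 0.38 in pairs 1 and 3. A part played by either cause is therefore not excluded. An effect of slide 2 as a whole is argued against, since pair 3, on the same slide, held 1271 genes changed at least 2-fold. The correlations across genes do not decide it. Pairs 1 and 3, on different slides, correlated more than pairs 2 and 3 on the same slide, by 0.30. Smaller changes by themselves lower a correlation, and pair 2 correlated at 0.427 with pair 3 against 0.368 with pair 1. A loss of short-lived mRNAs in pairs 1 and 3 was not settled by 400 zinc finger genes, which went both ways around medians of -0.094 and -0.062 in those pairs and -0.018 in pair 2. A weaker block of translation in replicate 2 also stays open. Host RNAs held low by nonsense-mediated decay had medians of 0.40 in pair 1, 0.23 in pair 3, short of the 0.3 set in advance, and -0.09 in pair 2. Their fitted changes over all arrays went both ways, with 9 of 14 above 0. A difference in exposure was not tested.

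The rise of the ATF4 list was weighed against array quality and the slide. Without the weak array of PBS replicate 3 the list's median was 1.06 times that of all 6 arrays, which argues against that array as the cause. Each slide held as many arrays of both groups, so a shift common to a slide's arrays could not give the rise. The slide test therefore adds only that the rise was seen on both slides, the smaller median being 0.52. A response to pirfenidone, or to the culture conditions that came with it, may account for it, as a hypothesis found and tested on the same data.

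Over all arrays the fall of the ribosomal proteins did not stand apart from that of equally bright genes, but within pairs this stays open. The list's median over all arrays was -0.206 against -0.203 for lists matched on signal, at percentile 35.6. This lay inside the range set in advance for a brightness trend, and quantile normalization alone left a median of -0.01. Within pairs 1 to 3 the list stood at percentiles 100, 1.9 and 0.26, with medians of -0.0067, -0.24 and -0.39 against -0.068, -0.20 and -0.33 for the matched lists. The matched lists were drawn gene by gene and hold no correlation between a list's genes, so these percentiles may be too extreme. The brightest of 5 classes of genes had a median of -0.13, against -0.01 in the dimmest. Pair 1 went the other way, at -0.0755 against -0.134, while pair 2 gave -0.113 against 0.0787 and pair 3 -0.177 against 0.0603. A response shared by all replicates is argued against, because the list's members in pair 1 had quartiles of -0.06 and 0.02.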
